A study of Ooceraea biroi with 96 samples.

How the data were processed

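Whole brains of single clonal raider ants (Ooceraea biroi) were profiled by RNA sequencing in 96 libraries. Per the labels, RNA was extracted with Tri reagent and libraries were made with a KAPA kit for stranded mRNA sequencing. The authors deposited 1 table of whole-number counts per gene, with gene coordinates, for the 96 libraries. Per the submitters' processing notes, reads were aligned with STAR 2.7.8a and assigned to genes with featureCounts. The strand setting, the handling of reads with several alignments and the genome build are not given in the sources used here. The deposited counts were not normalised, and the table holds 13755 features. Gene spans in the deposited table equalled those of the Obir_v5.4 RefSeq annotation for 100% of the features other than tRNA genes, so chromosome numbers and gene classes were taken from that annotation, and coordinates are those of the deposited table.

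Each library was assigned to 1 of 8 groups from its labels: the ant's own genotype (lineage B or M), the lineage of the colony it was reared in, and its age (1 or 8 days). Groups are written as genotype in environment, so that BinM is an ant of genotype B reared with lineage M. Replicates are separate individuals per the labels, but which individuals shared a colony is not given in the sources used here. P-values and intervals therefore treat individuals as independent. Day 1 replicates carry the numbers of their titles, and day 8 replicates are numbered in order of deposit. The 2 ages carry different forms of title and may have been handled as 2 sets, so age and set cannot be separated. Between libraries of a group, counts differed by far more than sampling noise (lowest chi-square per gene 9.465), and no library was treated as a duplicate.

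Total counts per library ranged from 10.7 to 26.96 megacounts. Protein-coding genes took 99.52% of all counts and long noncoding RNAs (lncRNAs) 0.4361%. Expression is given in CPM, the counts relative to each library's total as edgeR's cpm function gives them, scaled with TMM factors. Where all libraries of a group were at 0, a fold was bounded with a floor of 3 counts over that group's libraries. No molecular identifiers are named in the sources used here, so these floors cover counting error only. Intervals of fold changes from the main test also include the spread between individuals of a group.

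The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) on the deposited counts, with TMM scaling, the filterByExpr filter at its default minimum count of 10, robust dispersion and Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called. Each age was fitted with a 4-group model, on 9834 genes at day 1 and 9472 genes at day 8. Contrasts were genotype M minus B, social environment M minus B, their interaction, and the environment effect within each genotype. Age and its interactions were fitted in 1 model of the 8 groups on 10056 genes. Standard errors and 95% intervals of log2 fold changes were derived from the F statistics. The share of expression variance due to each factor and correlations of effects across genes were computed on log2 CPM with a prior count of 2 and tested with 100000 permutations of the labels of 1 factor within levels of the other. All adjusted p-values without another tool named come from edgeR.

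The procedure was tested on simulated data, in which counts were drawn from the means, library sizes and dispersions of the real libraries and 200 genes were changed, 50 per fold size. For the environment contrast, 58% of 1.25-fold, 82% of 1.5-fold and 88% of 2-fold changes were recovered at day 1, and 58%, 86% and 90% at day 8. For the interaction, 58% of 2-fold changes were recovered at day 1 and 82% at day 8. Simulated genes varied independently of each other, so structure shared by many genes of a library was absent. With 200 genes changed, a single change also passes the Benjamini-Hochberg adjustment more easily than where few genes change. Recovery in the real libraries may therefore be lower.

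Tests, alternatives and the rule for named genes were set before the data were examined unless said otherwise. With no product names at hand, the rule took, per contrast, the 2 largest positive and 2 largest negative changes among called genes with a mean of at least 1 CPM, all calls where few were made, and the 3 lowest p-values, given as values, where none was made. The annotation used here pairs no product names with the gene identifiers. The lists of gene functions fixed in advance were therefore void and none was tested. In their place, gene classes, chromosomes, runs of neighbouring genes and genes with counts almost only in 1 genotype were described. The limits for the last were a mean under 0.1 CPM against at least 1 CPM. All were chosen after the data were seen.

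Alternatives were DESeq2 size factors, library totals, no filter or a stricter filter (10 CPM in as many libraries as the smallest group), the DESeq2 1.42.0 Wald test, limma-voom (limma 3.58.1) with quality weights, dispersion without robust estimation, 2 surrogate variables (sva 3.50.0), an additive model, 1 fit of all 96 libraries, a replicate block, each library left out in turn, and outlying libraries left out. Outlying libraries had a median Spearman correlation with the other libraries of their age more than 3 scaled median absolute deviations below the median, or a total of less than the median divided by 3. There were 8 of them, 3 at day 1 (BinB replicate 9, MinB replicate 12 and MinM replicate 16) and 5 at day 8 (BinM replicate 2, MinB replicate 8 and MinM replicates 6, 9 and 12). They stayed in the main tests. Thinning all libraries of an age to the same total, leaving out single outlying libraries in the fit of the 8 groups, and all alternatives for genes called at both ages, for chromosome 13 and for neighbouring genes were added after the data were seen.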

Results

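Brain expression was measured in 96 individual clonal raider ants, a queenless species whose workers reproduce without mating. Newly hatched larvae of 2 clonal lineages, B and M, were placed in colonies of either lineage, so that an ant's own genotype and the genotype of its social environment varied independently. Brains were sampled at an age of 1 day (7 BinB, 9 BinM, 14 MinB and 20 MinM) or 8 days (10 BinB, 10 BinM, 12 MinB and 14 MinM). Library totals ranged from 13.9 to 25.34 megacounts at day 1 (median 17.69) and from 10.7 to 26.96 megacounts at day 8 (median 15.1). The number of genes with at least 1 count was lowest on average in MinB brains of day 8 (10717 ± 233 SD, n = 12) and highest in MinB brains of day 1 (10984 ± 130 SD, n = 14).

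The first comparison asked how an ant's own genotype affected brain expression. Genotype M and genotype B brains differed in 1452 of 9834 genes at day 1 (712 higher and 740 lower in M) and in 800 of 9472 genes at day 8 (394 higher and 406 lower in M). Most of these differences were small. Of the called genes, 1113 at day 1 and 561 at day 8 differed by less than 1.5-fold, and 170 and 123 differed by at least 2-fold. A few genes had counts almost only in 1 genotype. Whether they were unexpressed, missing or poorly matched by reads in the other genotype was not tested. The protein-coding gene LOC113562066 (chromosome 6, 8378774 to 8379678) had 0 counts in all 16 B libraries of day 1 and all 20 of day 8. In M it reached 11.6 CPM ± 1.95 (SD, n = 34) at day 1 and 10.6 CPM ± 3.31 (SD, n = 26) at day 8, at least 1070-fold and 1210-fold above the floor over the B libraries (edgeR adjusted p = 1.85e-32 and 3.14e-22). The lncRNA LOC113563188, near the start of chromosome 13 (26920 to 29494), had 1 count over all 16 B libraries of day 1 and 0 over the 20 of day 8, against 4.67 CPM ± 1.63 (SD, n = 34) and 3.03 CPM ± 1.37 (SD, n = 26) in M (adjusted p = 1.56e-25 and 1.74e-14).

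In the opposite direction, LOC113563356 (chromosome 14, 8277676 to 8283690) stood at 7.73 CPM ± 1.87 (SD, n = 16) in B and 0.0448 CPM ± 0.0548 (SD, n = 34) in M at day 1, a 163-fold difference of pooled rates, and at 9.52 CPM ± 1.31 (SD, n = 20) and 0.042 CPM ± 0.0464 (SD, n = 26) at day 8 (210-fold; adjusted p = 1.17e-28 and 1.48e-33). LOC113563270 (chromosome 13, 5481763 to 5484393) was 20.3-fold lower in M at day 1, at 27.4 CPM ± 4.82 (SD, n = 16) in B and 1.39 CPM ± 0.61 (SD, n = 34) in M (adjusted p = 8.3e-32). It overlaps another gene on the same strand, so its counts may include shared reads. LOC113563366 (chromosome 14, 320739 to 327381) was 140-fold lower in M at day 8, at 3.66 CPM ± 0.877 (SD, n = 20) against 0.0283 CPM ± 0.0542 (SD, n = 26) (adjusted p = 2.49e-24). It overlaps a gene on the other strand. By the limits of a mean under 0.1 CPM in 1 genotype and at least 1 CPM in the other, 5 genes were on in M alone and 3 in B alone at day 1, and 4 and 4 at day 8. Of these, 3 genes in each direction met the limits at both ages.

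**Figure D1:**
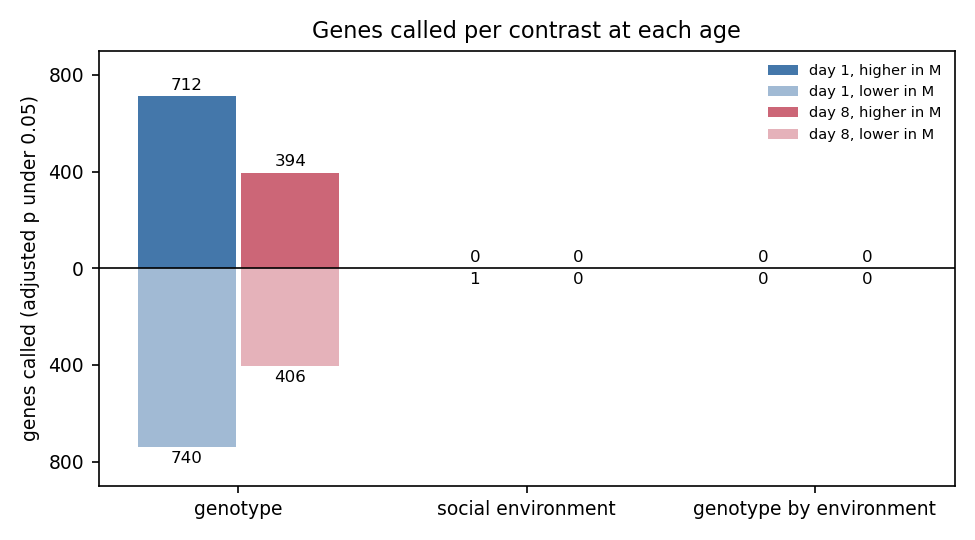
Number of genes called (adjusted p under 0.05, edgeR) for genotype, social environment and their interaction at day 1 (blue) and day 8 (red), with genes higher in M above 0 and genes lower in M below 0. Genotype bars reach 712 and 740 genes at day 1 and 394 and 406 at day 8, and the only other call is 1 gene lower in social environment M at day 1.

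Part of the genotype effects was shared between ages. Of 9404 genes tested at both ages, 368 were called at both, 355 of them with the same sign (165 higher and 190 lower in M), where 59.1 would be expected from independent lists. The ages share no library. The 368 genes were 26.2% of the 1406 day 1 calls and 46.6% of the 790 day 8 calls tested at both ages. Of the day 1 calls, 864 (61.5%) had the same sign at day 8, whether called there or not. These include the 355 genes called at both ages with the same sign. Among the 1038 genes called at day 1 alone, signs at day 8 were split about evenly between same and opposite. Over all genes the correlation was 0.683 (permutation p = 1e-05, the smallest that 100000 permutations can give). LncRNAs were called at both ages more often (29 of 445, 6.52%) than protein-coding genes (325 of 8933, 3.64%). The odds ratio of lncRNAs against other genes was 1.85 (95% interval 1.2 to 2.74, Fisher's exact adjusted p = 0.00872 over 3 classes). At a single age the excess of lncRNAs did not pass (adjusted p = 0.761 at day 1 and 0.06 at day 8). Over all genes, genotype accounted for 9.87% of expression variance at day 1 and 11.3% at day 8 (permutation p = 1e-05 for each, the smallest possible). Relabelled libraries gave mean shares of 2.1% and 2.23%. The second principal component at day 1 and the third at day 8 followed genotype most closely, which explained 55.1% and 51.6% of their variance. Genotype also explained 20.8% of the first and 25.9% of the second component at day 8. At day 1 it explained 12.5% of the fourth and 23.9% of the fifth.

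**Figure D2:**
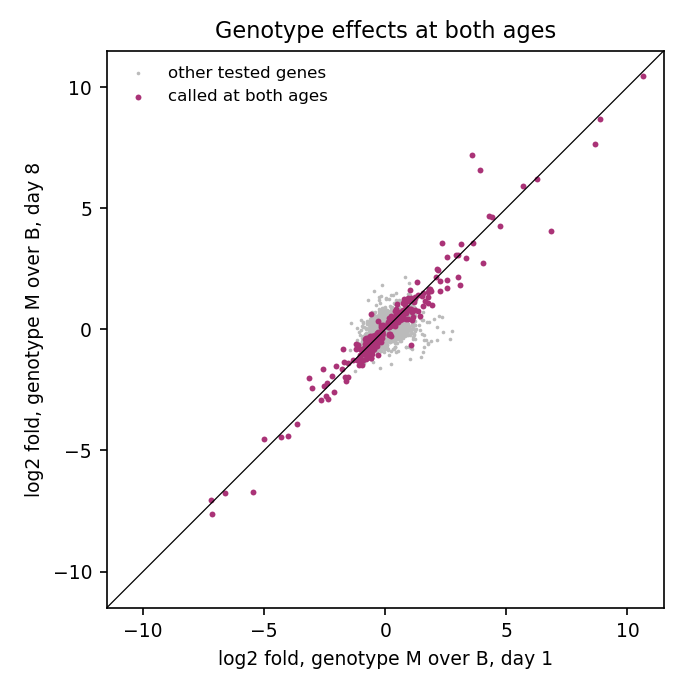
Log2 fold change of genotype M over B at day 1 (x axis) and day 8 (y axis) for each gene tested at both ages, with the line of equality. The 368 genes called at both ages (purple) lie close to the line except 13 with opposite signs, and other tested genes (grey) cluster around 0.

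Genotype calls occurred on all 14 chromosomes, with an excess on chromosome 13. There 42 of 343 tested genes (12.2%) were called with the same sign at both ages, against 313 of 9061 (3.45%) on the other chromosomes (odds ratio 3.9, 95% interval 2.7 to 5.52, Fisher's exact adjusted p = 1.32e-10 over 14 chromosomes). Of the 42 genes, 22 were higher and 20 lower in M. Fisher's exact test takes genes as independent, but called genes clustered along chromosomes, so its intervals may be too narrow and its p-values too small. On chromosome 8, 12 of 635 genes (1.89%) were called (odds ratio 0.473, 95% interval 0.241 to 0.844, adjusted p = 0.048), but its lower rate did not pass at day 1 (odds ratio 0.833, adjusted p = 0.658) or day 8 (odds ratio 0.686, adjusted p = 0.126) alone. Chromosome 13 also led at each age alone, with 25% of its genes called at day 1 and 19.2% at day 8. Neighbouring genes were called in the same direction more often than random placement would give: 172 pairs at day 1 (1.61 times the expected number), 76 at day 8 (2.25 times) and 38 among genes called at both ages (5.68 times; permutation p = 1e-04 for each, the smallest that 10000 permutations can give). The longest run held 5 consecutive genes in 59.5 kb of chromosome 9 (4342706 to 4402164). All 5 were higher in M, with log2 fold changes (mean of both ages) of 2.13 to 3.14. A run of 3 genes at the start of chromosome 11 (27614 to 268344) was lower in M by log2 fold changes of -6.09 to -4.22, and another run of 3 on the same chromosome (13022187 to 13030327) was higher in M by 1.64 to 4.49.

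The second comparison asked whether the genotype of the social environment affected brain expression. Almost no gene differed between ants reared with lineage B and ants reared with lineage M. At day 1 only LOC105283796 (chromosome 4, 14557104 to 14563516) was called, lower in environment M by a log2 fold change of -2.99 ± 0.48 (SE, adjusted p = 0.000848). The gene overlaps another on the other strand, and the strand setting of the counting is not given in the sources used here. The call rested on BinB replicate 2, which had 106 CPM where the other 6 BinB libraries had at most 4.26. Without that library the log2 fold change was -1.24 ± 0.32 (SE, adjusted p = 0.71). At day 8 the lowest p-values were those of LOC105281594 (log2 -0.99 ± 0.25 SE), LOC105287262 (log2 2.94 ± 0.77 SE) and LOC105287120 (log2 -1.33 ± 0.36 SE), which overlap other genes (edgeR adjusted p = 0.998 for each). LOC105287262 stood at 361 CPM in BinM day 8 replicate 10 and at most 2.15 CPM in the other BinM libraries of that age. At day 8 edgeR called 0 genes, as did DESeq2 and limma-voom, and 314 genes had an unadjusted p under 0.05 (636 with limma-voom) where 474 would be expected by chance. At day 1 that number was 655 against 492 expected. It was 702 with DESeq2, 782 with library totals and 862 with 2 surrogate variables, but 387 with limma-voom, 351 in the additive model, 225 with title numbers as a block and 193 without the 3 outlying libraries of that age. DESeq2 called 5 genes at day 1 and limma-voom 0.

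The intervals bounded the size of the environment effects averaged over the 2 genotypes, taking individuals as independent. If individuals of a colony were alike, the intervals would be too narrow. At day 1 the 95% interval lay within 1.5-fold for 8425 genes (85.7%) and within 2-fold for 94.6%, and at day 8 within 1.5-fold for 8426 genes (89%) and within 2-fold for 96.8%. Bounds within a single genotype were wider. Within genotype B the interval lay within 1.5-fold for 70.4% of genes at day 1 and 80.9% at day 8. Within genotype M these values were 83.5% and 82.9%. Smaller changes were not detectable for every gene at this depth and sample size. The social environment accounted for 1.69% of expression variance at day 1 (permutation p = 0.608) and 1.85% at day 8 (p = 0.516), where relabelled libraries gave means of 1.91% and 1.95%. No principal component among the first 5 of an age had more than 7.48% of its variance explained by environment. No correlation across genes was detected between environment effects in genotype B and in genotype M at day 1 (r = 0.0243, permutation p = 0.898) or day 8 (r = 0.136, p = 0.362), or between environment effects at the 2 ages (r = 0.2, p = 0.24). The last 2 values were 0.0445 and 0.0665 without outlying libraries and 0.206 and 0.354 with the stricter filter (p from 0.188 to 0.746). The central 95% of relabelled libraries spanned -0.354 to 0.35, -0.292 to 0.295 and -0.323 to 0.325, so a moderate correlation could not have been seen.

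**Figure D3:**
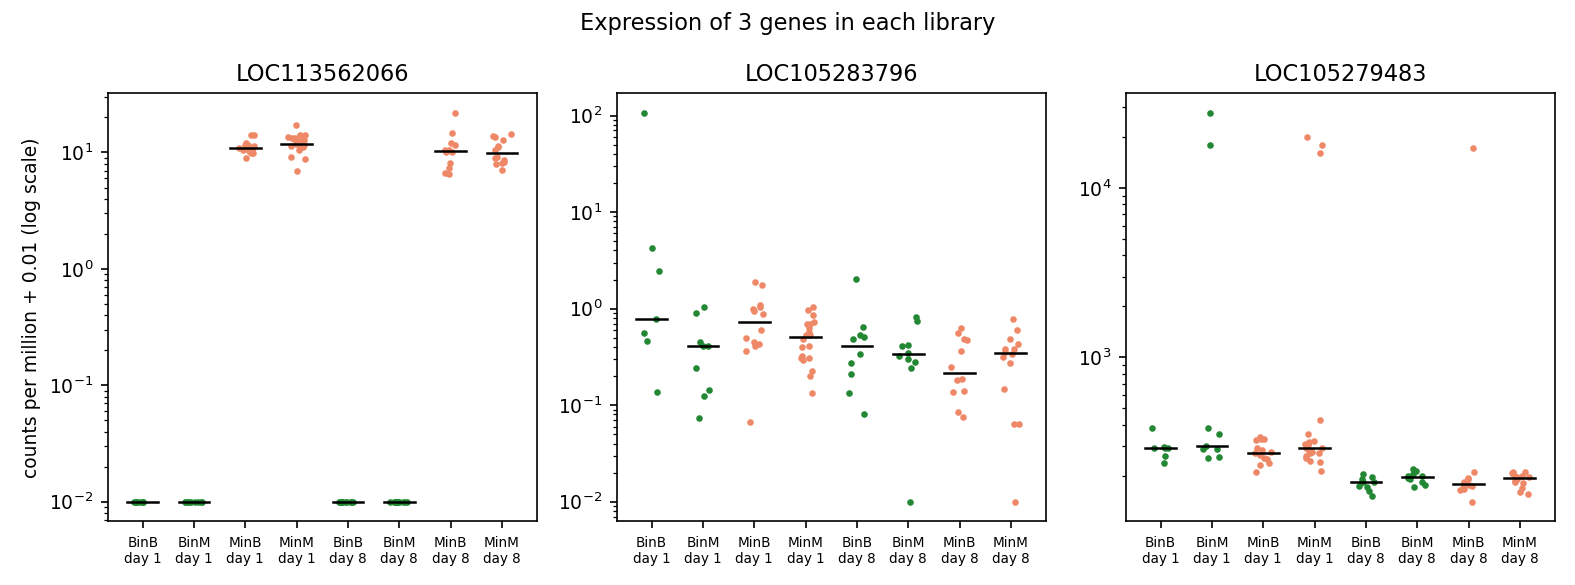
CPM plus 0.01 on a log scale for 3 genes in each library of the 8 groups (genotype B in green, genotype M in orange), with a line at each group's median. LOC113562066 is at 0 in all B libraries, LOC105283796 is high in 1 BinB library of day 1 (106 CPM), and LOC105279483 is at 16042 CPM or more in 6 libraries.

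Within genotype B at day 1, the only call was again LOC105283796 (log2 fold change -5.33 ± 0.81 SE, adjusted p = 0.000293), which without BinB replicate 2 had a log2 fold change of -1.82 ± 0.53 SE and an adjusted p of 0.458. In this contrast 984 genes had an unadjusted p under 0.05 where 492 would be expected. The number was 906 with limma-voom, 1026 with DESeq2 and 1155 with 2 surrogate variables, but 508 with title numbers as a block and 255 without the outlying libraries. DESeq2 called 3 genes and limma-voom 0. Within genotype M at day 1 edgeR called 0 genes (234 with unadjusted p under 0.05, and 374 with limma-voom), DESeq2 1 and limma-voom 0. The lowest p-values there were those of LOC105286989 (log2 -5.10 ± 1.06 SE) and LOC113561980 (log2 1.37 ± 0.29 SE), which overlap other genes (adjusted p = 0.096 for each), and LOC105283624 (log2 -2.25 ± 0.54 SE, adjusted p = 0.453), which overlaps none. LOC105283624 stood at 142 CPM in MinB replicate 3 and at most 16.3 CPM in the other MinB libraries. LOC105286989 stood at 273 CPM in MinB replicate 12, an outlying library, and at most 13.1 CPM in the other MinB libraries, with group medians of 0.0415 CPM (MinB) and 0.0565 CPM (MinM). At day 8 edgeR, DESeq2 and limma-voom called 0 genes in either genotype, with 147 (B) and 416 (M) genes at an unadjusted p under 0.05 in edgeR. These numbers were 305 and 698 with limma-voom, 227 and 634 with 2 surrogate variables and 211 and 641 without outlying libraries. Within B the lowest p-values were those of LOC105287262 (log2 5.24 ± 1.23 SE), LOC105287120 (log2 -2.02 ± 0.56 SE) and the lncRNA LOC105285038 (log2 -1.09 ± 0.32 SE), with an adjusted p of 1 for each. The lowest p at day 8 within M belonged to LOC105279483 (chromosome 9, 15605082 to 15639359, log2 fold change -3.08 ± 0.61 SE, adjusted p = 0.08), for which 1 MinB library reached 17162 CPM and no other library of day 8 more than 220 CPM. It was followed by LOC105286378 (log2 0.24 ± 0.06 SE) and LOC113562775 (log2 1.06 ± 0.27 SE), with an adjusted p of 0.968 for each.

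The interaction asked whether the effect of the social environment depended on the ant's own genotype. As coded, it is also 2 times the mean difference between ants reared with their own and with the other lineage. EdgeR called 0 genes at day 1 (614 with unadjusted p under 0.05, 492 expected) and 0 at day 8 (223, with 474 expected). The day 1 number was 1159 with limma-voom and 335 without outlying libraries, and the day 8 number 343 with limma-voom, 360 with 2 surrogate variables and 364 without outlying libraries. DESeq2 called 1 and 0, and limma-voom 0 and 0. The lowest p at day 1 was that of LOC105283796 (log2 4.68 ± 0.95 SE, adjusted p = 0.099), followed by LOC105279557 (log2 2.10 ± 0.55 SE, adjusted p = 0.723). BinB replicate 2 held the highest value of each, with 117 CPM of LOC105279557 where the other BinB libraries of day 1 had at most 9.51 CPM. At day 8 the lowest p-values were those of LOC105274732 (log2 -0.94 ± 0.26 SE) and LOC105279483 (log2 -3.18 ± 0.89 SE), which overlap other genes (adjusted p = 1 for each). The median 95% half-width of an interaction was 0.30 (log2) at day 1 and 0.28 at day 8, about double that of the environment effect (0.15 and 0.14). The doubling follows from the scale of the contrast. The mean difference between rearing with the own and the other lineage was therefore estimated about as precisely as the environment effect.

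More genes were called between ages than in any other contrast, in a fit of 96 libraries against 50 and 46 for the contrasts within an age. Between day 1 and day 8, 7347 of 10056 genes differed (3785 higher and 3562 lower at day 8). Large falls outnumbered large rises, with 633 genes at least 2-fold lower and 348 at least 2-fold higher, and 217 and 53 at least 4-fold. LOC105275422 (chromosome 3, 6449680 to 6453994) fell from 681 CPM ± 760 (SD, n = 20) in MinM brains of day 1 to 0.709 CPM ± 0.864 (SD, n = 14) at day 8 (log2 fold change over all groups -9.79 ± 0.51 SE, adjusted p = 1.27e-31). LOC109611483 (chromosome 5, 7171986 to 7173486) fell from 128 CPM ± 116 (SD, n = 20) to 0.0599 CPM ± 0.102 (SD, n = 14) in the same groups (log2 -10.57 ± 0.54 SE, adjusted p = 2.2e-32). Both genes varied widely among day 1 brains: LOC105275422 ranged from 1.04 to 2704 CPM within MinM. LOC105288145 (chromosome 10, 1256392 to 1270887) rose from 0.108 CPM ± 0.19 (SD, n = 20) to 23.5 CPM ± 22.1 (SD, n = 14) in MinM (log2 7.09 ± 0.45 SE over all groups, adjusted p = 2.6e-26). LOC105288082 rose by log2 7.85 ± 0.45 (SE, adjusted p = 2.95e-29), but it lies inside LOC105288145 on the same strand, so the 2 may share reads. The 2 ages carry different forms of title, and a difference between sets of libraries cannot be told from age. With library totals in place of TMM, 5184 genes were higher and 2450 lower at day 8, and the median log2 fold change of all genes moved from 0.01 to 0.14. With DESeq2 3583 were higher and 3809 lower.

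Genotype effects differed between ages in 643 genes (387 with a higher and 256 with a lower M over B ratio at day 8). The excess of higher ratios did not hold with limma-voom (142 higher and 166 lower), with 2 surrogate variables (240 and 232) or without outlying libraries (63 and 76). Of the 630 tested at both ages, 328 were called between genotypes at day 1 alone, 103 at day 8 alone and 39 at both. Without BinB day 1 replicate 9, 166 genes were called, without MinB day 8 replicate 8 379 and without MinM day 8 replicate 6 417 in this genotype by age interaction, and without all 8 outlying libraries 139. Of the 643 genes, 117 were also called without these 8. High values in 1 or a few libraries marked the genes named by the rule. LOC105277525 (chromosome 7, 4703712 to 4708402, log2 1.93 ± 0.6 SE, adjusted p = 0.0391) reached 26.2 CPM in MinM day 8 replicate 9 and at most 6.2 CPM elsewhere. LOC113561583 (an lncRNA on chromosome 1, 1369364 to 1372754, log2 1.54 ± 0.4 SE, adjusted p = 0.0186) reached 20.2 CPM in BinB day 1 replicate 9 and 35.8 CPM in MinB day 8 replicate 8. LOC105278024 (chromosome 1, 18815731 to 18822302, log2 -3.08 ± 0.92 SE, adjusted p = 0.034) reached 28.7 CPM in MinB day 1 replicate 12 and had a mean of 0.444 CPM ± 0.494 (SD, n = 20) in MinM brains of that age. LOC105286420 (chromosome 14, 4043848 to 4047443, log2 -2.79 ± 0.88 SE, adjusted p = 0.0424), which overlaps a gene on the same strand, had a mean of 6.08 CPM ± 14.5 (SD, n = 14) in MinB brains of day 1 and 0.85 CPM ± 1.36 (SD, n = 20) in MinM, and ranged up to 172 CPM at day 8. Without BinB day 1 replicate 9 none of these 4 genes was called: the log2 fold change was then -2.97 (adjusted p = 0.0722) for LOC105278024 in genotype by age interaction, -2.69 (0.0892) for LOC105286420 in genotype by age interaction, 1.71 (0.104) for LOC105277525 in genotype by age interaction and 0.81 (0.198) for LOC113561583 in genotype by age interaction. With limma-voom all 4 folds were smaller, at 0.63 (LOC105277525), 0.14 (LOC113561583), -0.76 (LOC105278024) and -0.97 (LOC105286420), and none was called (adjusted p from 0.49 to 0.81, the largest over the alternatives run).

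Environment effects differed between ages in 3 genes. LOC105283796 (log2 2.84 ± 0.59 SE, adjusted p = 0.0303) again held the value of BinB day 1 replicate 2. LOC105279945 (chromosome 3, 8839454 to 8841586, log2 5.59 ± 1.19 SE, adjusted p = 0.0307) stood at 24.7 CPM in that library and 72.4 CPM in BinM day 8 replicate 10, and at most 7.56 CPM in the others. LOC105279483 (log2 -5.27 ± 0.88 SE, adjusted p = 0.000398) was between 141 and 426 CPM in 90 libraries and between 16042 and 27784 CPM in 6, which were 2 BinM and 3 MinM libraries of day 1 and 1 MinB library of day 8. It overlaps a gene on the other strand.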

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

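The tests that left out single libraries for the age interactions, and the test that a single library decided the social environment call, were chosen after the result was seen.

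In groups of 10 or fewer libraries, a gap test of the highest and lowest library singled out 22 of 53 sets of values. The nominal rate of about 1 in 20 would give 2.65, but that rate assumes normally distributed values. Many sets were skewed CPM of genes named from these same libraries, some with 1 library above 0. The number singled out therefore has no chance level here and only describes the libraries. Several fell on BinB day 1 replicate 2, which was highest of its group for LOC105283796 (106 CPM), LOC109611483 (685 CPM), LOC105275422 (2470 CPM), LOC105279945 (24.7 CPM) and LOC105288082 (0.0484 CPM, with the others at 0). BinB day 1 replicate 9 had the lowest median Spearman correlation with other day 1 libraries (0.948), the lowest LOC113563356 (2.14 CPM) and LOC113563366 (0.214 CPM) and the highest LOC105279483 (384 CPM) of its group. BinB day 1 replicate 4 was highest for LOC105288145 (2.06 CPM). Among BinM libraries of day 1, replicate 9 was highest for LOC105288082 (0.113 CPM) and LOC105288145 (1.98 CPM), and replicate 8 held the only count of LOC113563188 (0.0635 CPM). Among BinB libraries of day 8, replicate 1 had the highest total (23.56 megacounts) and the most genes detected (11070), replicate 7 the highest LOC113563356 (12.9 CPM) and replicate 6 the highest LOC105283796 (2.04 CPM). BinM day 8 replicate 2 had the fewest genes detected (10046) and the lowest median Spearman correlation (0.9782) of its group. BinM day 8 replicate 5 was highest for LOC105288082 (20.5 CPM) and LOC105288145 (117 CPM), and replicate 10 for LOC105279945 (72.4 CPM).

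The single social environment call of day 1, LOC105283796, is likely the value of 1 library. Without BinB replicate 2 its adjusted p was 0.71 (log2 fold change -1.24 ± 0.32 SE, against -2.99 ± 0.48 SE with it), so both the size and the call changed. Over all 62 alternatives the log2 fold change lay between -3.14 and -1.24 and the call was lost in 5, with adjusted p up to 1. The same library was the highest of its group for other named genes too. A smaller effect of the social environment on this gene stays open, since the value without that library did not pass the test but was not 0. The test of the difference between ages called 3 genes: LOC105283796 (log2 2.84), LOC105279945 (log2 5.59) and LOC105279483 (log2 -5.27). In each, 1 to 6 libraries held values far above the rest. The fit of the 8 groups was not run without those libraries, so whether these calls depend on them was not tested.

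Genotype effects differed between ages in 643 genes, among them LOC105277525 (log2 1.93), LOC113561583 (log2 1.54), LOC105278024 (log2 -3.08) and LOC105286420 (log2 -2.79). A candidate explanation for most of these calls is a few outlying libraries: without them 21.6% of the number was called, and without BinB day 1 replicate 9 alone 166 genes. Lost calls alone do not show that the effects came from these libraries. Of the 643 calls, 561 (87.2%) had the sign of the deviation of BinB day 1 replicate 9 from its group, against 69.2% of other genes. The median size of that deviation was 0.593 (log2) in called and 0.529 in other genes. This library enters the tested effect, so an excess of equal signs is partly built in. Without BinB day 1 replicate 9, LOC105278024, LOC105286420 and LOC105277525 lost their call with little change in fold, while the fold of LOC113561583 became smaller. Folds of the other called genes without it are not given here. A difference between the 2 sets of libraries also stays open: 18.4% of the 630 genes tested at both ages were called at day 8 alone or with opposite signs, but the limit set in advance assumed more noise at day 8, and the median SE of the genotype effect was larger at day 1 (0.0735 against 0.069). A difference in how far the 2 genotypes had matured at day 1 stays open: the genotype effect at day 1 and the age effect from other libraries gave a permutation p of 0.449 (r = 0.166), but the central 95% of relabelled libraries spanned -0.361 to 0.339, so a correlation of moderate size could not have been seen and the limit on p set in advance excludes nothing. A genotype difference that changes with age stays open as well. This holds for the 117 of these genes that were also called without the outlying libraries. It also holds for the others, whose lost calls do not show that such a difference is absent.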

How the results depend on the processing

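The tests on thinned counts, those on genes called at both ages, and the 8-group fits without single outlying libraries were chosen after the data were seen. The genotype count at day 1 stayed within 1.5 times the main value under every alternative run (992 to 1673 calls), as did the age count (5739 to 7869). The genotype count at day 8 fell to 515 with the stricter filter, which tests fewer genes, and otherwise lay between 720 and 1112, and the 355 genes called at both ages with the same sign fell to 203 with that filter. Calls of the genotype by age interaction fell from 643 to 308 with limma-voom and to 139 without outlying libraries. Without single outlying libraries this count ranged from 166 (without BinB day 1 replicate 9) to 765, with 379 without MinB day 8 replicate 8 and 417 without MinM day 8 replicate 6. The age count then ranged from 7320 to 7463, and the count of environment effects differing between ages from 3 to 6 (without MinM day 1 replicate 16). The last count was 1 with the stricter filter, with limma-voom and with surrogate variables, and 5 without outlying libraries.

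The environment counts stayed at 8 or fewer throughout, and the causes of their changes were not tested. The day 1 environment count of 1 became 4 with library totals, 7 with no filter, 5 with DESeq2, 3 without robust dispersion, 5 without outlying libraries, 8 in 1 fit of all libraries, 2 in the additive model, 2 after thinning, and 0 with the stricter filter, limma-voom and surrogate variables. Within genotype B at day 1 the count of 1 became 3 with DESeq2, 7 without outlying libraries, 8 in 1 fit of all libraries, and 0 with the stricter filter and limma-voom. Within genotype M at day 1, and for the interaction at day 1, the count of 0 became 1 with DESeq2 and 1 in 1 fit of all libraries. At day 8 the count within genotype M became 3 with no filter and 1 without robust dispersion, and the environment count and that within genotype B became 1 in 1 fit of all libraries. Leaving out single libraries gave 1138 to 1673 genotype calls at day 1 and 720 to 836 at day 8. It gave 0 (BinB replicate 2) to 6 (BinB replicate 7) environment calls at day 1, with 2 (MinB replicates 9, 11, 12 and 13), 3 (BinB replicate 1, BinM replicates 1 and 10, MinB replicate 5), 4 (BinB replicates 3 and 4) and 5 (BinB replicates 6 and 9, MinB replicate 7, MinM replicate 16). Within genotype B at day 1 it gave 0 (replicate 2) to 5 (BinB replicate 4), within genotype M 0 to 1 (BinM replicate 5 or MinM replicate 19), and for the interaction 0 to 1 (BinB replicates 3, 4, 6 and 7). At day 8 it gave 0 for the environment, the interaction and genotype B, and 0 to 1 within genotype M, with 1 when any MinB library except replicate 7 was left out.

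The correlation of environment effects between genotypes at day 1 (0.0243) turned to -0.00249 with the stricter filter and -0.0768 without outlying libraries, with permutation p-values of 0.993 and 0.679. Other shares, correlations and size bounds kept their side of the threshold, and the genotype genes named by the rule kept their call under each alternative that tested them. Whether day 1 title numbers pair the libraries stays open. Deviations of same-numbered libraries correlated at a median of 0.0473 over 52 pairs, 20 of which were above 0.1, against -0.00298 for different numbers. Of 44 libraries, 7 correlated best with their own number, and no chance level was computed for these values. With the replicate block, 992 genotype calls, 0 environment calls and 0 within genotype B were made at day 1, and the interaction and genotype M counts stayed at 0. No paired analysis was possible at day 8 because each number occurs once there. The gene lists fixed in advance, and their alternatives, were not run because no product names were at hand. Depth and number of libraries limited small changes: of simulated interactions at day 1, 36% of 1.5-fold and 96% of 4-fold changes were recovered.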

Other observations

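The tests on lowered genes in outlying libraries, on direction by genotype and on windows of chromosome 13, and the threshold for LOC105279483, were chosen after the result was seen.

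Individual brains of 1 group differed in ways the labels do not record. Among day 1 brains, genes that rise at least 2-fold with age (348) and genes that fall at least 2-fold (633) moved against each other. Within groups, their mean levels correlated at Pearson's r = -0.438 (permutation p = 0.00181, adjusted p = 0.00362 over 4 tests, n = 50) and Spearman's rho = -0.392 (permutation p = 0.00659). Without the 2 most extreme libraries r was -0.285, and without outlying libraries -0.586. The central 95% of random gene sets of the same sizes spanned -0.0221 to 0.732. Among day 8 brains the correlation was positive (r = 0.392, permutation p = 0.00824, adjusted p = 0.011, n = 46), within the range of random sets (-0.243 to 0.704), and 0.104 without outlying libraries (permutation p = 0.542). A candidate explanation, tested on the same libraries that defined the genes, is that individuals sampled at day 1 had matured to different degrees.

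LOC105279483 lay at 1 of 2 separate levels in each individual: 6 of 96 libraries held at least 1000 CPM (16042 to 27784), up to 2.64% of a library's counts, and the other 90 held 141 to 426 CPM (median 214). None of the 6 was an outlying library. Of the 6, 5 came from environment M (53 libraries) and 1 from environment B (43 libraries), a division that did not pass Fisher's exact test (p = 0.219, adjusted p = 0.328 over 3 factors; p = 0.206 for age and 1 for genotype). At day 1 alone, 5 of 29 libraries of environment M and 0 of 21 of environment B were high (Fisher's exact p = 0.0657).

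The 8 outlying libraries had up to 462 genes at least 4-fold lower (BinB day 1 replicate 9) or up to 402 at least 4-fold higher (MinB day 1 replicate 12) than the mean of their group's other libraries. The median over the 88 other libraries was 28 lower and 24 higher, but the highest among them (195 lower and 240 higher) overlapped the outlying ones, such as MinM day 8 replicate 12 (172 lower and 16 higher). The median pair of them shared 5.42 times as many lowered genes as independent sets of equally likely genes would. Pairs of the 88 other libraries from different groups shared 8.34 times as many (median of 3337 pairs), so the ratio does not show that the outlying libraries changed together. BinB day 1 replicate 9, MinB day 8 replicate 8 and MinM day 8 replicate 6, from 3 groups, were the most alike, with deviations correlating across genes, which are not independent replicates, at r = 0.443 to 0.62. No biological explanation was tested.

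For the genes called between genotypes, depth, overlapping genes and outlying libraries were weighed first. After thinning to equal totals at least 90.1% of the number of calls was made, genes that overlap no other gene were called at 98.1% or more of the rate of all genes, and without outlying libraries at least 89.8% of the number of calls was made at each age, with 1045 of the 1452 genes (72%) called again at day 1 and 694 of 800 (86.8%) at day 8. Reads of 1 genotype matching the reference less well stay open. Of the genes called at both ages 53.5% were lower in M (95% Wilson interval 48.3 to 58.6), but TMM scaling centres the log ratios, so an even split would be seen in either case and the limit set for it decides nothing. Runs of neighbouring genes that changed together (permutation p = 1e-04, the smallest possible) leave open changes that span several genes, such as a deletion, a duplication or a shared regulatory region, for part of the calls. Neighbouring calls also exceeded random placement for age (1.12 times, permutation p = 1e-04) and genotype by age (1.73 times, p = 7e-04), against 5.68 times for genotype at both ages. Overlapping neighbours were not set apart, so the excess alone does not point to a deletion or duplication.

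The excess of genotype calls on chromosome 13 did not rest on a single block of 2 Mb. With each of 343 windows of 2 Mb left out in turn, the weakest excess was that without 5271839 to 7271838, where 31 of 307 genes (10.1%) were called at both ages against 3.45% on other chromosomes (odds ratio 3.14, one-sided Fisher's exact p = 2.77e-07). This p-value, too, takes neighbouring genes as independent and may be too small. Larger or several blocks were not tested. Under the 5 alternatives run, the odds ratio of chromosome 13 ranged from 3.35 to 4.81, and neighbouring calls from 3.61 to 5.72 times the chance number. What sets chromosome 13 apart was not tested.

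Mean distance of libraries to their group's centre did not differ detectably between social environments (smaller permutation p of the 2 ages 0.287) or genotypes (0.213). At day 1 it was 0.474 ± 0.147 (SD, n = 21) in environment B and 0.454 ± 0.0876 (SD, n = 29) in environment M. At day 8 it was 0.4 ± 0.0823 (SD, n = 20) in genotype B and 0.444 ± 0.134 (SD, n = 26) in genotype M. With this spread, differences larger than those seen stay open.

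Refitting 100 splits of the same libraries, the real one included, argued against a chance split of individuals for the counts of genotype at each age and of age. The splits exchanged individuals as if independent. Which individuals shared a colony is not given, so chance differences between colonies were not tested. Only 1 of 100 splits reached the real count for genotype at day 1 (1452 calls, highest other split 13), genotype at day 8 (800, highest other 4) and age (7347, highest other 1028). The same held for genotype effects that differ between ages (643, highest other 429), but this does not exclude chance for a difference between ages. Those splits exchanged genotype labels within environment and age, which removed the genotype effect itself as well. They do not test a genotype effect that is equal at both ages. In addition, 166 genes were called without BinB day 1 replicate 9 and 139 without the outlying libraries, both below 429, and no splits were run without them. A chance split of individuals stays open for the other counts. Of the 100 splits, 17 gave at least the 1 environment call of day 1 (highest other 148), 39 the 1 call within genotype B at day 1 (highest other 1028) and 20 the 3 environment effects that differ between ages (highest other 619). For counts of 0 all 100 splits reach the real value by construction; the highest others were 17 (interaction, day 1), 47 (within M, day 1), 2 (environment, day 8), 6 (interaction and within B, day 8) and 268 (within M, day 8). Splits with many times the real count point to a structure of the samples beyond the groups, the source of which was not tested.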
